A study of Mus musculus with 4 samples.

How the data were processed

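Gamma delta intraepithelial lymphocytes were sorted from the colon of conventionally raised C57BL/6 mice. There were 2 samples from untreated mice and 2 from mice given 2% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium, for 5 days and then normal water for 3 days. Total RNA was isolated with the PicoPure kit, amplified with the RiboAmp HS kit and labelled with biotin, per the labels' protocols. Each sample was hybridised to 1 array, read in 1 colour. Nothing in the labels says whether replicates came from separate animals, pools or sorts, so p-values measure only the spread between these samples, which may be technical.

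The deposited values are linear intensities, 1 signal per probe set and array, from 45101 probe sets of an Affymetrix-style 3' expression array. They were made with GCOS, per the submitters' processing notes, and its version, algorithm and settings are not given in the sources used here. The deposited intensities of each array average 500 after the lowest and highest 2% are dropped, so each array had been scaled to a common trimmed mean. No detection calls were used here. The median signal was 193.8 and 213.9 on the untreated arrays and 157.1 and 163.3 on the DSS arrays. The number of arrays limits the precision.

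A platform table paired the probe sets with genes. Of the probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 had none, the 64 control probe sets included. By gene number, 34754 of those with 1 symbol matched a second table of mouse genes, which updated 0 symbols. Probe sets with several symbols or none were not named. Names ending in _x_at or _s_at mark probe sets that can bind related transcripts, so values read on them are uncertain. Among the genes named, these include Lyz1, H2-Aa, Tnfaip2, Ms4a6d, Ctsh, C1qb, Maf, Zap70, Itgae, Laptm5, Hspa8 and Pomc. Values of other lysozyme, H2, Klra and immunoglobulin genes are treated as uncertain too, although Lyz2 and H2-Eb1 were read on probe sets without these endings.

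Signals were analysed as log2(signal + 32) with no further normalization. A probe set was kept if it exceeded the median of its own array on at least 2 of the 4 arrays. Each gene was represented by its kept probe set with the highest mean, which left 12424 genes. Fold changes are on the log2(signal + 32) scale, which understates changes of dim genes. DSS was compared with untreated in R 4.3.3 by limma 3.58.1 (lmFit and eBayes with an intensity trend), with group as the only term and Benjamini-Hochberg adjustment at 0.05. Genes whose DSS arrays both lay at least 2-fold above or below both untreated arrays were counted without a test, and the same count was made for the other splits of the 4 arrays into pairs.

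Gene lists covering lymphocyte functions, stress and metabolism, and 9 other cell types were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested members. Camera with a correlation estimated from the residuals and limma's fry were run beside it. List members were adjusted over all genes and again over the list alone. The lists, tests, main settings and 19 other settings were fixed before the data were examined. A further 2 settings, giving 3 recomputed results, were chosen after seeing the data: genes with an arithmetic mean signal of 1000 to 20000, and lists without members of the macrophage and neutrophil lists. The other settings covered scaling, pseudocount, filter, probe set choice, variance model, threshold, replicate block and leaving out each array.

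The genes named were to be the 8 with the largest log2 change in each direction among those that passed. Because none passed, the rule's fallback applied: the 8 genes with the largest moderated t in each direction whose groups did not overlap, given as values only. For each list, at most the 2 members with the smallest limma p were named. Csf1r, C1qb, Mpeg1, Fcgr4, Ccl5 and Mmp8 were named after their values were seen, as were the genes of a second macrophage list in the closing observations.

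The limma step was tested on data simulated for the comparison of DSS with untreated over 12424 genes, with 200 changed genes in each of 20 simulations. It recovered 0% of log2 changes of 1, 1.1% of changes of 2, 20.4% of changes of 3 and 54.8% of changes of 4, and 6.6% of its calls were false. Camera at the preset correlation called 0.05 lists on average when none was shifted. It found the cell cycle list, of 31 tested genes, in 85% of simulations when that list was shifted by 0.5. No other list was shifted, so this share does not hold for shorter lists. These simulated genes varied independently of each other and had the same spread in both groups.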

Results

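Genome-wide transcript levels were measured in gamma delta intraepithelial lymphocytes, T cells that reside within the gut epithelium, sorted from untreated and from DSS-treated mouse colon. Each group had 2 arrays, and 12424 genes were compared. The comparison addresses how these lymphocytes' transcripts differ after DSS injury and 3 days of recovery.

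Across genes, which are not independent replicates, the DSS arrays correlated at r = 0.92 with each other and the untreated arrays at r = 0.794. Arrays of different groups correlated at 0.817 to 0.854. The median absolute log2 difference was 0.685 between the untreated arrays, 0.361 between the DSS arrays and 0.526 to 0.689 between arrays of different groups. The standard deviation between replicates was 0.82 log2 in untreated and 0.52 in DSS samples. The hybridisation controls are the bioB, bioC, bioD and cre transcripts added before hybridisation. Their signals were 5.83-fold higher on the untreated arrays, at 44427 and 29832 against 6308 and 6192. This difference follows the groups. Differences between DSS and untreated samples therefore cannot be separated from differences in how their arrays were processed. The 100 brightest probe sets held 25.5% and 24.2% of the summed signal on the untreated arrays, and 12.9% and 15% on the DSS arrays. The 3'-to-5' signal ratio of Actb was 14.7 and 23.0 on the untreated arrays and 16.0 and 10.6 on the DSS arrays.

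**Figure D1:**
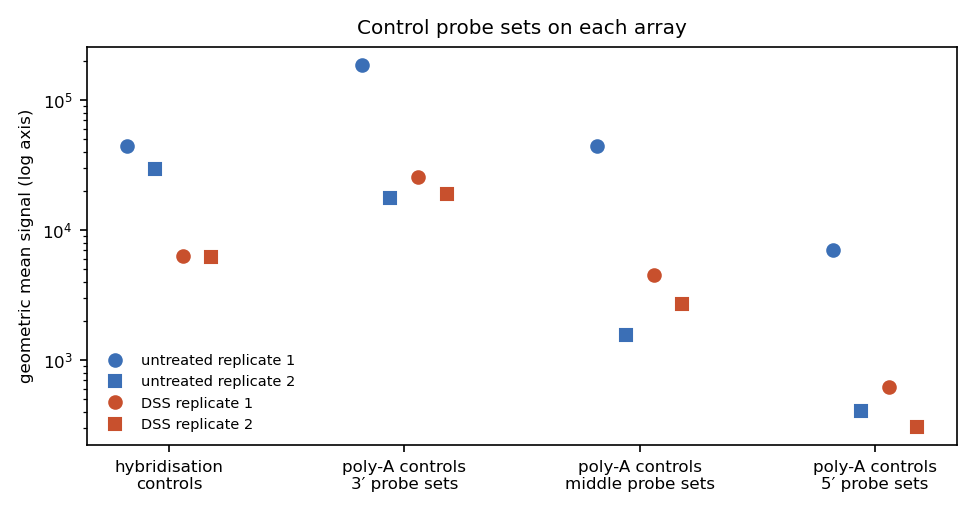
Geometric mean signal (log axis) of the control probe sets on each of the 4 arrays, with circles for replicate 1 and squares for replicate 2. Hybridisation controls lay at 44427 and 29832 on the untreated arrays and at 6308 and 6192 on the DSS arrays, while the 3' poly-A controls stood at 186215 on untreated replicate 1 and at 17845 to 25874 on the other arrays.

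The 8 genes with the largest moderated t toward higher signal in the DSS samples included a cytokine, a lysozyme and a lysosomal protease. Il1b, a proinflammatory cytokine, had signals of 365 and 354 in untreated and 5862 and 7134 in DSS samples, a log2 difference of 4.05 ± 0.38 (SE, n = 2 per group). Ms4a6d differed by 4.39 ± 0.44, and Ly86 (MD-1), which pairs with the Toll-like receptor homologue RP105, by 4.55 ± 0.47. Saa3, an acute-phase serum amyloid A protein, differed by 4.60 ± 0.60, Ifitm1, an interferon-inducible membrane protein, by 4.43 ± 0.54, and Ctsh, the lysosomal protease cathepsin H, by 4.13 ± 0.56. Lyz1, a lysozyme, had 1294 and 167 in untreated and 32381 and 50414 in DSS samples, with a log2 difference of 6.30 ± 0.83. Tnfaip2 differed by 5.42 ± 0.50 on its brightest probe set, but its other probe sets gave -1.81 and 0.10.

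Lower signals in the DSS samples were found for genes of varied function. Cd8b1, the beta chain of the CD8 coreceptor, had 722 and 727 in untreated and 137 and 98.6 in DSS samples, a log2 difference of -2.35 ± 0.47. Amotl2, an angiomotin family protein, differed by -2.84 ± 0.53, Ahdc1 by -2.91 ± 0.55, and Abcb8, a mitochondrial transporter, by -2.52 ± 0.49. Pde11a, a cyclic nucleotide phosphodiesterase, differed by -3.01 ± 0.62 and Zfp14, a zinc finger protein, by -2.03 ± 0.42. Laptm5, a lysosomal membrane protein of blood cells, differed by -1.64 ± 0.33 on its brightest probe set, with other probe sets between -0.19 and 1.91. Pomc differed by -2.48 ± 0.52, and by 1.28 on its other probe set. On both DSS arrays Amotl2, Ahdc1, Abcb8, Cd8b1, Pde11a and Pomc lay below the array medians of 157.1 and 163.3. Dim genes were lower in DSS samples as a class, which limits what these values can show.

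None of these differences passed adjustment: limma called 0 of 12424 genes, with a smallest adjusted p of 0.0823, shared by Tnfaip2, Il1b, Ms4a6d and Ly86. At unadjusted p under 0.05 there were 461 genes higher and 473 lower in DSS samples, 934 in all, where 621.2 are expected by chance. Limma called 3 genes (Il1b, Ly86 and Ms4a6d) when a gene's probe sets were averaged, 1791 without untreated replicate 1 and 755 without untreated replicate 2. It called 0 without either DSS array and under each other scaling, pseudocount, filter and variance model run. With the replicate number as a block limma called 67 genes, 61 higher and 6 lower, but the numbers are not taken as pairing. In a count without a test, 271 genes lay at least 2-fold higher and 296 at least 2-fold lower on both DSS arrays than on both untreated arrays, 567 in all. The other splits of the arrays gave 227 and 219. The share of these genes that were higher was 47.8% as deposited, 61.6% after quantile normalization and 75.4% after scaling to a common median, and the median log2 difference of all genes was -0.07, 0.01 and 0.25 in turn. The groups did not overlap for 41% of genes, against 33.3% by chance.

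**Figure D2:**
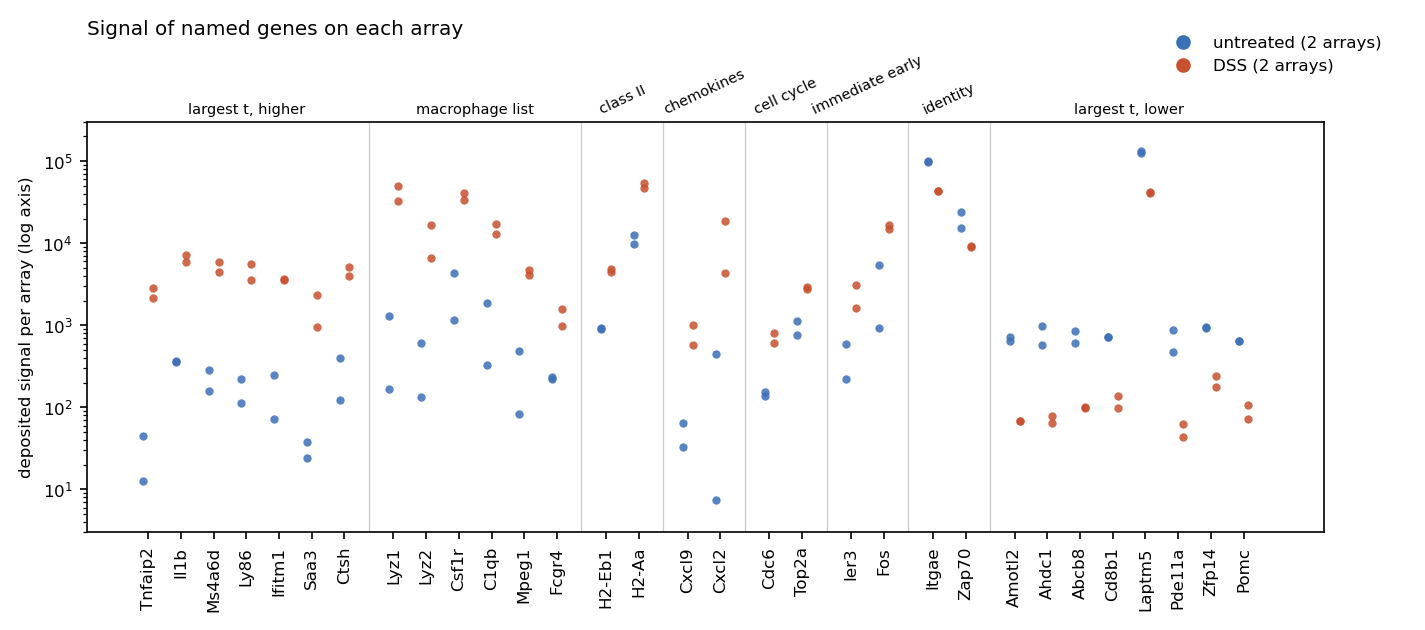
Deposited signal (log axis) of named genes on each array, with 1 point per array, blue for untreated and red for DSS, and genes grouped by the rule or list that named them. Il1b lies at 365 and 354 on the untreated and at 5862 and 7134 on the DSS arrays, and Cd8b1 at 722 and 727 against 137 and 98.6. Cd8b1 is below the median signal of both DSS arrays.

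Differences depended on signal level. Genes with a mean signal of 222 to 292 had a median log2 difference of -0.33 and those of 3500 to 7060 a median of 0.19, while the 125 genes of 29900 or more had a median of -0.46. Ccl5, Laptm5, Itgae and Hspa8 all have their named probe set in that brightest class. Among the 3956 genes with an arithmetic mean signal of 1000 to 20000, 69 lay at least 2-fold higher and 13 at least 2-fold lower on both DSS arrays. An arithmetic mean admits genes that reach 1000 through 1 group alone, such as Tnfaip2, so these counts may partly reflect that choice. In the log2 classes from 1090 to 29800 the counts were 19, 14, 6 and 4 higher and 9, 1, 1 and 1 lower, from dim to bright.

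**Figure D3:**
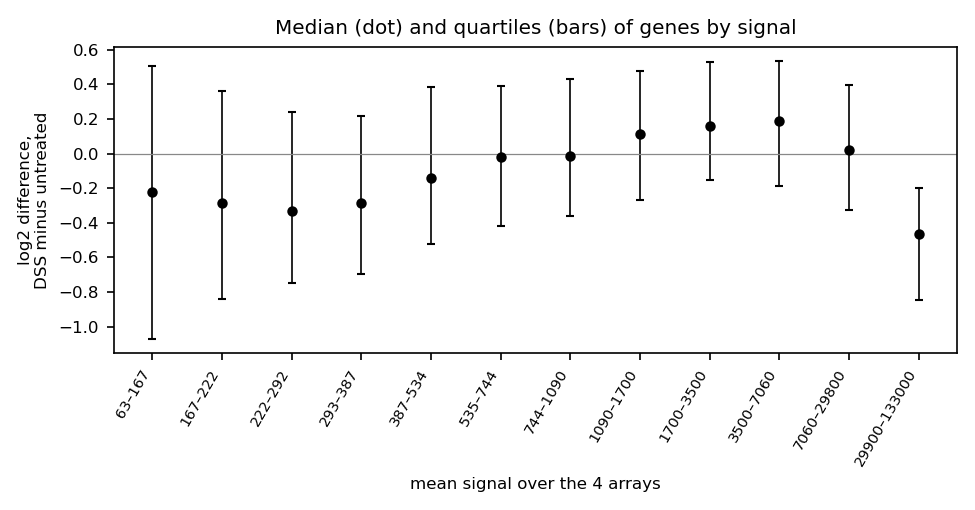
Median (dot) and quartiles (bars) of the log2 difference, DSS minus untreated, of genes in 12 classes of mean signal over the 4 arrays. The median runs from -0.33 in genes of 222 to 292 through 0.19 in genes of 3500 to 7060 to -0.46 in the brightest 125 genes.

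Gene lists were compared to ask which functions and which cell types' transcripts shifted together. Of 35 lists, 12 shifted higher in DSS samples by camera at the preset correlation and 0 shifted lower. In the other splits of the arrays, each of which puts 1 untreated with 1 DSS array, camera passed 0 and 3 lists. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.411, and 2 lists had an unadjusted p under 0.05. That form of camera tests on the 2 residual degrees of freedom, so a list could hardly pass it whatever its correlation. Class II genes, with an estimated correlation of -0.063 against the preset 0.01, did not pass either. Failing this form therefore does not decide whether a list shifted. The class II correlation was the lowest among the called lists. The highest was 0.211, for immediate early genes, and macrophage and dendritic cell markers had 0.127. Where members vary together more than the preset assumes, camera's p-values at the preset are too small. Fry called 1 list, lipid and cholesterol metabolism. For every list, 0 members passed limma when adjusted over all genes, so members are given below as values and as counts adjusted over the list alone.

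Macrophage and dendritic cell markers had the largest median of the 35 lists, a log2 difference of 1.75 over 25 genes (camera adjusted p = 5.46e-15; adjusted p = 0.411 with an estimated correlation). Of these genes 20 were higher on both DSS arrays than on both untreated arrays, and 13 passed, all higher, when adjusted over the list alone. Lyz2, the lysozyme of macrophages and neutrophils, differed by 5.00 ± 0.73. Csf1r, the receptor for macrophage colony-stimulating factor, had signals of 4342 and 1162 in untreated and 33267 and 40991 in DSS samples. It differed by 4.02 ± 0.62 on this brightest probe set and by 2.69 and 1.52 on the others. C1qb, a complement C1q chain, and Mpeg1, the pore-forming perforin-2, both differed by 4.18, with standard errors of 0.75 and 0.69, and the Fc receptor Fcgr4 by 2.29 ± 0.43. The neutrophil list also shifted higher, with a median of 1.39 over 15 genes, 11 higher and 4 lower (adjusted p = 0.000193; adjusted p = 0.411 with an estimated correlation). The 5 that passed, adjusted over the list alone, included Il1b and the neutrophil-attracting chemokine Cxcl2, which differed by 6.05 ± 1.17 with untreated signals of 443 and 7.49, and both of which macrophages also make. The neutrophil granule collagenase Mmp8 differed by -1.85 ± 0.92 and was lower on both DSS arrays, with signals of 231 and 240 against 23.7 and 66.6. It is a dim gene: the array medians were 193.8 and 213.9 in untreated and 157.1 and 163.3 in DSS samples. As dim genes were lower in DSS samples as a class, its value carries little weight.

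Antigen presentation by MHC class II shifted higher, with a median of 1.32 over 12 genes (adjusted p = 1.62e-05; adjusted p = 0.411 with an estimated correlation). H2-Eb1, a class II beta chain, had 916 and 889 in untreated and 4799 and 4424 in DSS samples, a log2 difference of 2.31 ± 0.37. The class II alpha chain H2-Aa differed by 2.18 ± 0.36, and 4 members passed adjusted over the list alone. Chemokines shifted higher with a median of 0.87 over 20 genes (adjusted p = 0.000104; adjusted p = 0.411 with an estimated correlation). Adjusted over the list alone, 6 chemokines were higher and 1 lower. The interferon-induced Cxcl9 differed by 3.32 ± 0.61, while Ccl5 (RANTES), which is abundant in these lymphocytes, differed by -1.48 ± 0.34 with signals of 166892 and 171899 against 55885 and 65842. Ccl5 has 1 probe set, in the brightest class of genes, whose median was -0.46, and it differed by -0.25 after quantile normalization. Both lists were higher in the same DSS samples as the macrophage markers, and each shares 1 member with the macrophage or neutrophil lists. Whether they vary with those markers was not tested.

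The interferon response list shifted higher by a median of 0.53 over 31 genes (adjusted p = 0.00162; adjusted p = 0.55 with an estimated correlation), with Cxcl9 and Cxcl10 (2.41 ± 0.76) leading, and 1 member passed adjusted over the list alone. Pattern recognition and NF-kB genes shifted by 0.38 over 26 genes (adjusted p = 0.0266; adjusted p = 0.411 with an estimated correlation). Tnfaip3 (A20), an inhibitor of NF-kB signalling, differed by 2.43 ± 0.50 on its brightest probe set and by -0.93 on the other, and Cd14, the lipopolysaccharide coreceptor, by 2.38 ± 0.51. Adjusted over the list alone, 4 of these genes were higher and 1 lower. Lipid and cholesterol genes shifted by 0.26 over 24 genes (adjusted p = 0.00304; adjusted p = 0.411 with an estimated correlation; fry adjusted p = 0.0387). The cholesterol exporter Abca1 (2.13 ± 0.46 on its brightest probe set and -0.10 on the other) and Apoe (2.39 ± 0.54), which macrophages also express, were the 2 that passed adjusted over the list alone. Without the 1 member it shares with the macrophage and neutrophil lists, the pattern recognition list no longer passed (camera adjusted p = 0.0799). As its adjusted p was 0.0266 with that member, the lost call does not show that the shift came from it. The interferon and lipid lists share 0 members with the macrophage and neutrophil lists.

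Cell cycle genes shifted higher, with a median of 0.56 over 31 genes and 27 higher estimates (adjusted p = 2.17e-06; adjusted p = 0.411 with an estimated correlation). The DNA replication licensing factor Cdc6 differed by 2.05 ± 0.46. Topoisomerase Top2a differed by 1.60 ± 0.40 on its brightest probe set, with signals of 759 and 1134 against 2800 and 2951, and by 0.27 on the other. The list shares 0 members with the macrophage and neutrophil lists, and 0 passed adjusted over the list alone. It was higher in the same DSS samples as the macrophage markers, and whether it varies with them was not tested. Immediate early genes, which also respond to tissue dissociation, shifted by 1.04 over 20 genes (adjusted p = 3.28e-06; adjusted p = 0.411 with an estimated correlation). Ier3 differed by 2.52 ± 0.57 and Fos by 2.78 ± 0.76, and 4 members passed adjusted over the list alone. Inhibitory receptors and regulators shifted by 0.80 over 20 genes (adjusted p = 0.00119; adjusted p = 0.411 with an estimated correlation). Its leading members, Tnfaip3 and the phosphatase Dusp1 (1.71 ± 0.48), are general feedback regulators and not receptors. The 1 member that passed adjusted over the list alone was Tnfaip3, whose probe sets disagree.

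Heat shock and chaperone genes shifted by 0.58 over 20 genes (adjusted p = 0.000819; adjusted p = 0.411 with an estimated correlation), with 0 passing adjusted over the list alone. The inducible Hspa1a differed by 2.83 ± 0.66. Its constitutive relative Hspa8 differed by -1.27 ± 0.34 on its brightest probe set, by 0.27 to 2.63 on the others, and by 0.09 after quantile normalization. Apoptosis genes shifted by 0.20 over 21 genes (adjusted p = 0.0499; adjusted p = 0.411 with an estimated correlation), with Cdkn1a (p21) at 1.41 ± 0.46 and 0 passing adjusted over the list alone. The immediate early, inhibitory, heat shock and apoptosis lists each share 0 members with the macrophage and neutrophil lists, as do the cell cycle, interferon and lipid lists. All of these were higher in the same DSS samples as the macrophage markers. Whether any of them varies with those markers was not tested. Camera no longer called the apoptosis list after quantile normalization, although its median was then 0.39, or in 9 more of the 16 alternatives run for lists.

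**Figure D4:**
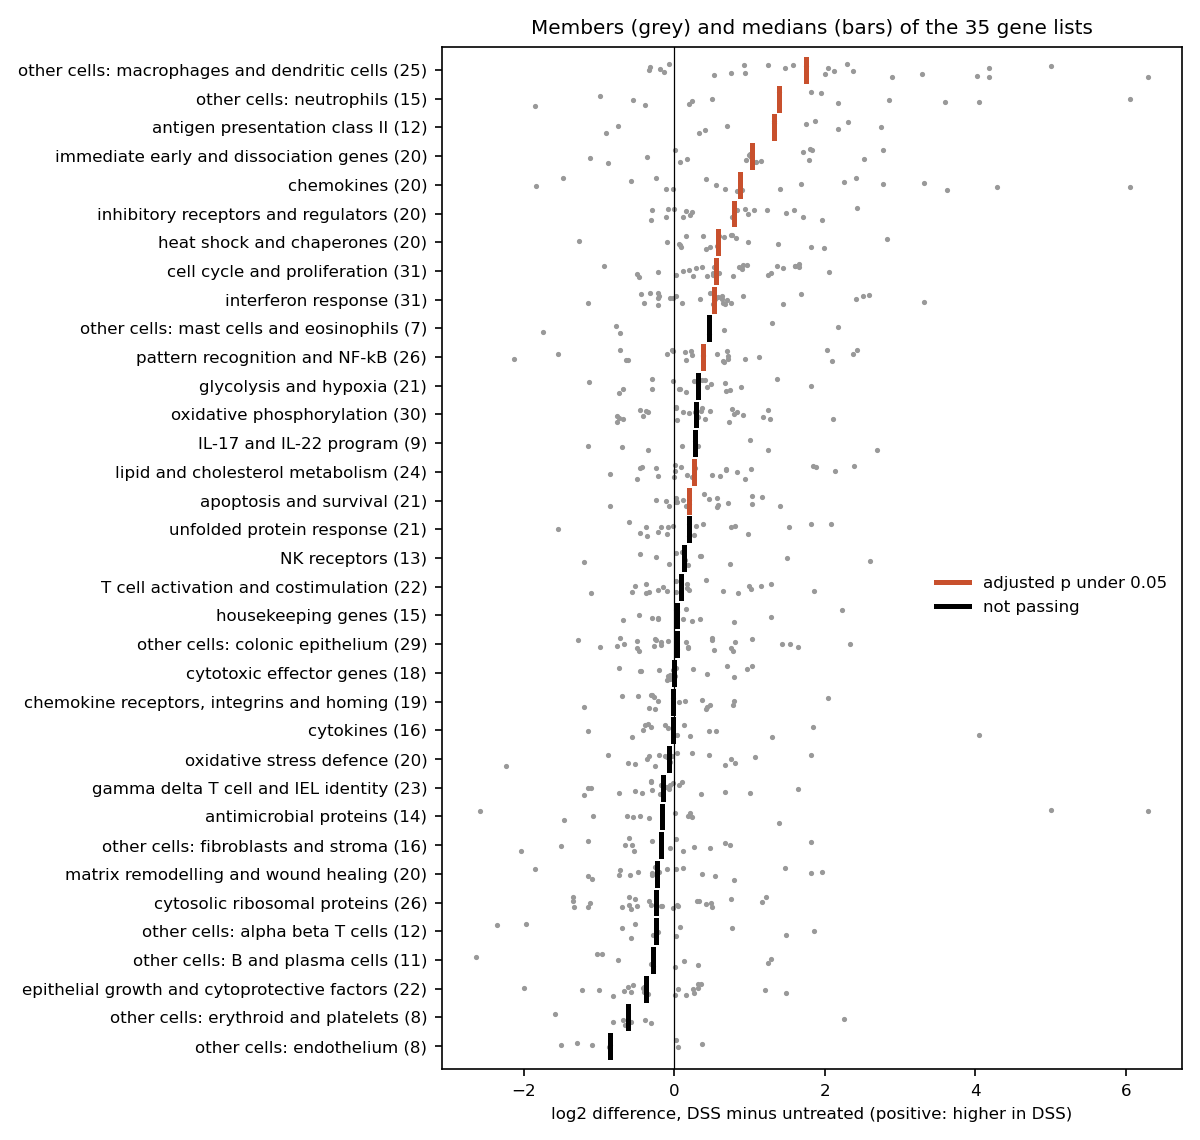
Log2 difference of DSS minus untreated for the tested members (grey points) and median (bar) of each of the 35 lists, with the number of tested members in brackets. Red bars mark the 12 lists past an adjusted p of 0.05 by camera at the preset correlation, led by macrophage and dendritic cell markers at a median of 1.75.

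Lists of lymphocyte identity and effector genes did not pass. The gamma delta T cell and intraepithelial lymphocyte identity genes had a median of -0.15 over 23 genes as deposited and after quantile normalization, and 0.18 after common-median scaling (adjusted p = 0.413), with 0 passing adjusted over the list alone. Trgv4 (-0.52) was the only gamma delta receptor gene of that list tested, and 2 of its members are also in the macrophage list. The list therefore does not set gamma delta cells apart from other T cells. Itgae (CD103), the integrin that anchors these cells to epithelium, differed by -1.20 ± 0.33 on its brightest probe set and by 0.52 on its other probe set. The T cell receptor kinase Zap70 differed by -1.10 ± 0.39 on its brightest probe set, with others up to -0.24. Cytotoxic effector genes had a median of -0.01 over 18 genes, 0.20 after quantile normalization (adjusted p = 0.369), the 2 with the smallest p being Ctsc (0.97 ± 0.38) and Lamp1 (0.80 ± 0.37). Among 13 NK receptor genes (median 0.14; adjusted p = 0.232) Klrc1, encoding NKG2A, differed by 2.60 ± 0.45, with signals of 179 and 159 against 910 and 1544, and was the 1 member that passed adjusted over the list alone. Cytokine genes had a median of -0.02, 0.32 after common-median scaling, and a mean of 0.33 over 16 genes (adjusted p = 0.316), and Il1b was the 1 that passed adjusted over the list alone. The IL-17 and IL-22 program had a median of 0.28 over 9 genes (adjusted p = 0.316), with the transcription factor Maf (2.69 ± 0.62) the 1 passing adjusted over the list alone.

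Lists tied to epithelial repair did not pass either. Epithelial growth and cytoprotective factors had a median of -0.37 over 22 genes as deposited and 0.08 after quantile normalization (adjusted p = 0.376), with keratinocyte growth factor Fgf7 at -1.23 ± 0.55. Matrix remodelling and wound healing genes had a median of -0.23 over 20 genes, 0.05 after quantile normalization, although camera's direction was up (adjusted p = 0.978). Antimicrobial proteins had a median of -0.17 and a mean of 0.44 over 14 genes, and a median of 0.14 after common-median scaling (adjusted p = 0.641). The 2 of them that passed adjusted over the list alone were the lysozymes Lyz1 and Lyz2. Cytosolic ribosomal proteins had a median of -0.24 over 26 genes and 0.35 after quantile normalization (adjusted p = 0.232).

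Of the 9 lists of other cell types, macrophages and neutrophils were the 2 that passed camera at the preset correlation, and 0 passed with an estimated correlation. Colonic epithelial genes had a median of 0.04 over 29 genes (adjusted p = 0.531). Alpha beta T cell genes had a median of -0.25 over 12 genes, and 0.02 after quantile normalization (adjusted p = 0.627). Cd8b1, below the median signal of both DSS arrays, was the 1 that passed, lower, adjusted over the list alone. B and plasma cell genes had a median of -0.28 over 11 genes and 0.02 after common-median scaling (adjusted p = 0.735). Endothelial genes had a median of -0.86 over 8 genes (adjusted p = 0.211), fibroblast and stroma genes -0.17 over 16 genes, turning to 0.15 after common-median scaling (adjusted p = 0.444), and mast cell and eosinophil genes 0.46 over 7 genes (adjusted p = 0.488). Erythroid and platelet genes had a median of -0.62 over 8 genes (adjusted p = 0.527), with the platelet factor Pf4 at 2.26 ± 0.45, higher and passing adjusted over the list alone.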

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

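Of the tests below, those of scaling and of the lymphocytes' own transcription were chosen only after the macrophage result was seen. Among 4259 probe sets without a single gene name, which no comparison above used, 76 lay at least 2-fold higher on both DSS arrays than on both untreated arrays and 169 at least 2-fold lower, against 130 and 122 in both directions for the other splits of the arrays.

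The macrophage list shifted higher in the DSS samples by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.411), and 0 of its members passed when adjusted over all genes. The form with an estimated correlation could hardly pass, as it tests on 2 residual degrees of freedom. Scaling of the arrays as its whole cause is argued against, since the fixed list's median of 1.75 stood at percentile 100 of 10000 random lists matched on mean level, whose highest median was 0.57. Random genes need not vary together as the list's members may, so this compares the list with its signal level only. None of the other fixed lists was compared in this way. Macrophages or dendritic cells carried through the sort for gamma delta cells are a hypothesis that stays open: a second list, holding 54 genes absent from the fixed lists, of which 42 were tested, had a median of 0.95, short of the 1 set in advance, at percentile 100 of its own random lists (highest median 0.44), which met the other condition, with 23 genes higher and 4 lower on both DSS arrays. Of its 4 members with the highest mean signal, Npc2 differed by 0.11, Pltp by -0.97, Selenop by 1.40 and Ctsb by 0.94. Transcription by the lymphocytes after injury, the biological explanation the design gives, may also account for the macrophage list's shift. The T cell identity genes' median of -0.15 favours neither, since a small share of carried-over cells would leave it near 0 too. The share of such cells was not estimated. With no cell counts or sort purity analysed here, these explanations cannot be told apart.

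The brightest probe sets were lower in the DSS samples: 54 genes had a probe set with a mean over 50000, with a median log2 difference of -0.80, and 42 of them were lower on both DSS arrays. A lower signal ceiling on the DSS arrays after scaling is a candidate explanation. In 33 of these genes other probe sets with means of 1000 to 20000 had a median of 0.33 ± 0.07 (SE) against -0.96 for the brightest ones. All genes with means in that range had a median of 0.14, so part of the contrast belongs to the range. The lower values of Itgae, Ccl5, Laptm5 and Hspa8 fall in this class. Except for Ccl5, they were read on _x_at or _s_at probe sets, and binding of related transcripts was not tested. No biological explanation was tested.

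Dim genes also had lower values in the DSS samples. Noise on the untreated arrays, raised with the signal when arrays were scaled, is a candidate explanation: 331 probe sets of genes of other tissues, such as olfactory receptors, had a median of -0.40 ± 0.05 (SE), against -0.21 for other probe sets of the same level (95% range -0.305 to -0.121). Their median signals were 97.0 and 112 on the untreated and 67.0 and 71.7 on the DSS arrays. No biological explanation was tested, and counts of genes lower in DSS samples may hold such noise.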

How the results depend on the processing

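No gene passed limma under quantile or common-median scaling, other pseudocounts, other filters, other variance models, all probe sets taken singly, or means of 1000 to 20000. Exceptions were 3 genes, all 3 higher, with probe sets averaged and 4 at adjusted p under 0.1. With the replicate number as a block 67 passed (61 higher, 6 lower), but same-numbered arrays deviated together only at r = 0.05 over 2 pairs, so the numbers are not taken as pairing, and the block changed no list call. Leaving out 1 array gave 0 to 1791 calls (0 to 1132 higher, 0 to 659 lower). The 1791 and 755 came without untreated replicate 1 and 2, when the lone untreated array is assumed to vary like the more alike DSS pair. Both fits use the same DSS arrays, so their calls are not independent.

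Genes at least 2-fold apart numbered 476 higher and 155 lower with common-median scaling, and 151 and 69 with a filter at the 75th percentile. The lower count was 172 with a pseudocount of 100, 497 without a filter and 445 over same-numbered arrays (replicate block, no test). With arithmetic means of 1000 to 20000, chosen after seeing the data, the counts were 69 and 13. Leaving out 1 array gave 367 to 1336 higher and 665 to 1064 lower, with fewer pairs to satisfy.

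With an estimated correlation, tested on 2 residual degrees of freedom, 0 lists passed. Of 192 list calls retried, 164 held, 28 were lost and 0 turned. Macrophage, neutrophil, class II, chemokine, cell cycle, immediate early, heat shock and lipid lists failed only with the estimated correlation. Apoptosis passed in 6 of 16 alternatives, pattern recognition in 11, interferon in 13 and inhibitory regulators in 14. Without members shared with the macrophage and neutrophil lists, also chosen after seeing the data, 10 lists passed, these 2 intact; of the others, only class II and chemokines lost a member (1 each) and passed. Ribosomal proteins passed as 1 lower list at the 75th percentile filter (adjusted p = 0.0345). Leaving out 1 array gave 9 to 15 lists, 0 to 1 of them lower (identity genes without untreated replicate 1, adjusted p = 0.0417; ribosomal proteins without DSS replicate 2, adjusted p = 0.0393).

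Of the named genes, 9 values turned. Quantile normalization gave Hspa8 0.09, Rps18 0.18 and Pgk1 0.06. These were read on probe sets of the brightest class. The highest deposited signals were 281602 and 250101 on the untreated arrays and 80427 and 100455 on the DSS arrays. Quantile normalization gives every array the same distribution, which raises the brightest DSS signals relative to the untreated ones. Averaged probe sets gave Laptm5 0.19, Hspa8 0.52, Apaf1 -0.01 and Pgk1 0.14, since their probe sets disagree. Tnfaip2 was -2.20 with a pseudocount of 1 and Pomc 0.81 with 100, when another probe set had the highest mean. Signal over background limits dim genes, whose differences depend on the pseudocount.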

Other observations

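Energy and stress lists not described above had small shifts that did not pass camera. Oxidative phosphorylation genes had a median log2 difference of 0.29 over 30 genes (adjusted p = 0.0836), with the ATP synthase subunits Atp5b at 1.27 ± 0.41 and Atp5j at 0.91 ± 0.38. Glycolysis and hypoxia genes had a median of 0.32 over 21 genes (adjusted p = 0.0816), with hexokinase Hk2 at 1.82 ± 0.51. The hypoxia factor Hif1a differed by 1.37 ± 0.51 on its brightest probe set, with others down to 0.13. Unfolded protein response genes had a median of 0.19 over 21 genes (adjusted p = 0.308), with Chac1 at -1.55 ± 0.56. Pdia3 differed by 1.52 ± 0.44 on its brightest probe set and by 0.18 on the other. Oxidative stress defence genes had a median of -0.08 over 20 genes, 0.27 after common-median scaling (adjusted p = 0.733). In these 4 lists 0 members passed adjusted over the list alone.

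T cell activation and costimulation genes had a median of 0.09 over 22 genes (adjusted p = 0.157). The costimulatory receptor Icos differed by 1.86 ± 0.53 on its brightest probe set and by -0.35 on the other. Egr3 differed by 1.15 ± 0.41 on its brightest probe set and by 0.25 on the other. Chemokine receptor, integrin and homing genes had a median of -0.02 over 19 genes, 0.33 after common-median scaling (adjusted p = 0.733), with the monocyte receptor Ccr2 at 2.04 ± 0.82 on its brightest probe set and others down to -0.40. Housekeeping genes had a median of 0.04 over 15 genes (adjusted p = 0.413), with Gusb at 2.23 ± 0.66. In these lists, too, 0 members passed adjusted over the list alone.

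Genes standing at least 4-fold below all other arrays numbered 179 on untreated replicate 1 and 157 on untreated replicate 2, against 67 and 69 on the DSS arrays. A test of whether parts of transcripts far from the 3' end were lost on untreated replicate 2 met its prediction, set in advance: other probe sets of 26 of the genes were lower by a median of 0.20 ± 0.31 (SE), against 3.02 for the probe sets used. It is not read as evidence of such loss, a decision taken after its result was seen. Noise of single probe sets predicts the same outcome, untreated replicate 1 gave -0.28 ± 0.41 against 3.16 in 11 genes, and no probe positions were measured.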
